A study of Homo sapiens with 6 samples.

How the data were processed

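RNA sequencing of polyadenylated RNA was available for 6 libraries of A549 cells, 3 labelled as control ASO and 3 as ZNF252P ASO, and groups and replicate numbers were taken from the sample titles. The titles call the reagent an ASO, while the column names of the ZNF252P ASO group carry the letters si, and the column names differ in style between the groups. The deposited table holds raw read counts per gene, not normalized, with 1 column per library for 60664 Ensembl gene IDs. The submitters' processing notes name HISAT2 2.0.4 without a role. The counting program, genome build, annotation release, strand setting and any filter are not given in the sources used here. Columns were matched to libraries through the sample descriptions, and 0 value columns belonged to no library. No row lacked a gene, and 28903 genes had no read in any library.

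Gene symbols came from a table of Ensembl IDs and names, in which 60463 IDs matched. Positions, gene types, exonic GC percent and exon overlap came from GENCODE 29, in which 58396 IDs matched. The GC percent is that of the longest transcript of each gene. For each gene the share of exonic length under exons of other genes was computed for the opposite and for the same strand. Exons of the IDs that did not match were not seen. A gene with no opposite-strand exon is therefore one with none in GENCODE 29. Because the strand setting is not known, overlapping and antisense genes are uncertain throughout, as are genes with near-identical copies.

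Genes were kept with edgeR's filterByExpr (15743 genes), scaled with TMM factors and tested between the groups with edgeR's robust quasi-likelihood test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. CPM are read counts scaled to the library total times its TMM factor, and means are given with the SD of 3 libraries. Standard errors are the log2 fold change divided by the square root of the F statistic. For genes with no read in a group a floor of 3 counts over the group was used, and for those with 1 to 3 reads an exact binomial interval of 95%. Both cover counting error only, since the reads carry no stated molecular identifiers. Folds given with a floor or an interval are ratios of scaled read counts, while the other folds of single genes are those edgeR fitted. An exact permutation test of single genes was not used, because 3 against 3 libraries cannot give a p under 0.10.

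The 33 gene lists were written from general knowledge before the data were examined, and 837 of 838 entries matched a gene. Lists with at least 3 tested members were compared with all other genes by limma's camera on log2 CPM (prior count 2, preset correlation 0.01, two-sided), adjusted over 31 lists. Alternatives were camera with an estimated correlation and fry. The genes named are ZNF252P, MYC, their neighbours and network members, and the 10 largest rises and 10 largest falls with a symbol, a mean of at least 5 CPM in a group and no overlap between groups. From each list past the threshold up to 3 members with the smallest adjusted p in its direction and 1 in the other direction are named, and from each other list up to 2. The values of 1 gene that this rule picks are not reported. Members named beyond that, where 5 or fewer of a list shared an outcome, were chosen after their values were seen. So were HK2 among the MYC target genes and the fully covered genes.

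Alternatives fixed beforehand were DESeq2 size factors, library totals and upper-quartile factors in place of TMM, no filter beyond 1 read, a filter of at least 1 CPM in 3 libraries, DESeq2's Wald test, limma-voom, a stricter adjusted p of 0.01, the replicate number as a block, and leaving out each library. Chosen after seeing the data were genes with no opposite-strand exon, a GC correction and both together. The GC correction was a loess per library with a span of 0.5, used as an offset. It was fitted on GC percent to the deviation of log2 CPM from the gene's mean over the 6 libraries. It therefore takes out any GC trend between the groups, whatever its source. In those runs, genes with no opposite-strand exon were scaled and tested apart from the others. A GC value was available for 99.3% of the genes tested.

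Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom from 2.70 to 8.35), so none was taken as a library deposited 2 times. That test does not show that the libraries came from separate cultures, and the 6 were used as separate samples because the labels list them so. The procedure was tested on simulated counts for 15743 genes with 200 changed genes, for the ZNF252P ASO against control ASO comparison. It recovered 46 of 67 genes changed 1.5-fold, 54 of 67 changed 2-fold and 62 of 66 changed 4-fold, with 10 calls among 15543 unchanged genes. With a simulated GC trend, 8962 unchanged genes were called without the GC correction and 10 with it. That trend was a straight line, which the loess correction is built to remove, so this does not show how well it works on the data. In the data 77.29% of genes were called, so scaling where most genes change was not tested. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.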

Results

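Gene expression was measured by RNA sequencing of polyadenylated RNA in A549 cells, an established human lung adenocarcinoma line. By the sample titles the cells had received either an ASO against ZNF252P or a control ASO. ASO is the usual abbreviation of antisense oligonucleotide, a short synthetic strand that pairs with an RNA and can lead to its breakdown. Each of the 2 groups held 3 libraries, and the deposited values were read counts for 60664 genes. The counts summed to 19416000 ± 1893000 (SD, n = 3) per control ASO library and to 18439000 ± 1926000 (SD, n = 3) per ZNF252P ASO library, with a range over the 6 libraries from 16240794 to 21503650. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

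The comparison of the 2 groups asks how the A549 transcriptome differed after the ASO against ZNF252P, and the series title names c-Myc. ZNF252P, a transcribed zinc finger pseudogene, was 3.35-fold lower in the ZNF252P ASO libraries, at 7.63 ± 0.305 CPM (SD, n = 3; CPM is the read count scaled to the normalized library total) against 25.5 ± 1.17 CPM (SD, n = 3) in the control ASO libraries. MYC, which encodes the transcription factor c-Myc, was 2.03-fold lower, at 196 ± 8.55 CPM (SD, n = 3) against 397 ± 66.6 CPM (SD, n = 3). For both genes, all 3 ZNF252P ASO libraries lay below all 3 control ASO libraries. The log2 fold change was -1.74 (SE 0.098) for ZNF252P, with an adjusted p of 9.3e-14 in edgeR's quasi-likelihood test. For MYC it was -1.02 (SE 0.12), with an adjusted p of 5.2e-05 in the same edgeR test. The ZNF252P values rest on 125 to 151 reads per ZNF252P ASO library and 449 to 577 reads per control ASO library. ZNF252P (ENSG00000196922) lies on the minus strand of chromosome 8 from 144973589 to 145002895, and MYC (ENSG00000136997) on the plus strand of the same chromosome from 127735434 to 127741434 in GENCODE 29 (GRCh38). Exons of genes on the opposite strand cover 11.7% of the exonic length of ZNF252P and none of MYC. After a correction for GC content, chosen after seeing the data, the log2 fold changes were -1.39 for ZNF252P and -1.29 for MYC.

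**Figure D1:**
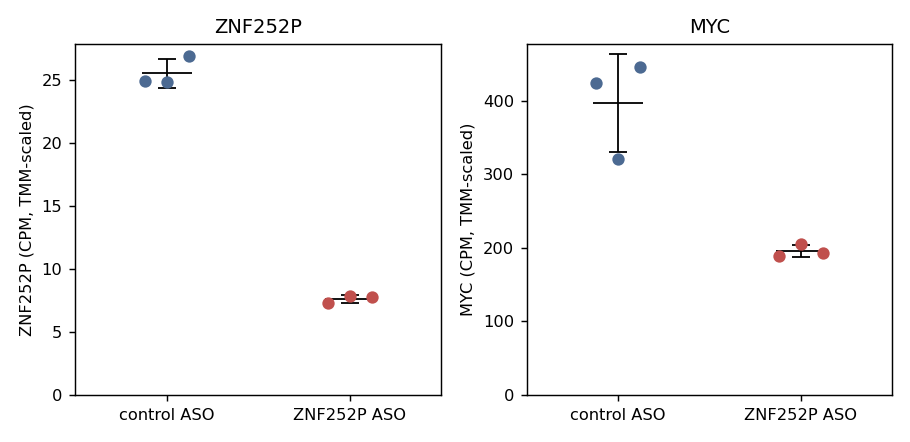
ZNF252P (left) and MYC (right) in CPM in each library of the control ASO and ZNF252P ASO groups, with a dash for the mean and bars for the SD of 3 libraries. ZNF252P averaged 25.5 CPM in the control ASO libraries and 7.63 CPM in the ZNF252P ASO libraries, and MYC 397 CPM and 196 CPM.

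Most of the measured transcriptome differed between the groups. Of 15743 genes tested, 6012 were higher and 6156 lower in the ZNF252P ASO libraries (edgeR, adjusted p under 0.05), which is 77.29% of the genes. By at least 2-fold, 2437 genes were higher and 2737 lower, and 57.48% of the called genes changed by less than that. The first principal component held 90.8% of the variance and parted the groups. Correlations of log2 CPM were at least 0.991 within a group and at most 0.897 between groups.

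Part of these differences followed gene structure. Among genes with under 2% of their exonic length under same-strand exons of other genes, those with no exon on the opposite strand had a median log2 fold change of 0.067 (8282 genes), and the median was -0.62 where opposite-strand exons covered 25 to 50% of the exonic length (577 genes) and -1.97 at 50 to 75% (150 genes). Of 44 genes covered completely, 41 had no read in any ZNF252P ASO library, among them SFT2D3, ZNF593, DND1 and HYI, and all 44 had reads in the control ASO libraries. Over all 9347 genes with no opposite-strand exon, scaled and tested on their own whatever their same-strand overlap, 3593 were higher and 3513 lower. Fold changes also rose with GC content, from a median of -0.64 in the lowest decile to 0.75 in the highest over 5520 coding genes with no exon overlap and a mean log2 CPM above 2 (Spearman's rho 0.494 across genes, which are not independent replicates). GC trends were also present between libraries of 1 group, where deviations from the group mean correlated with GC content at -0.388, 0.463 and -0.134 for ZNF252P ASO replicates 1, 2 and 3 and at 0.189, -0.123 and -0.0175 for control ASO replicates 1, 2 and 3. With the GC correction, 5835 genes were higher and 5986 lower, and 84.43% of the 12168 genes called without it were called again, 480 of them in the opposite direction. The labels give no batch, the column names differ in style between the groups, and a batch that goes with the group cannot be told apart from the ASO in this design.

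**Figure D2:**
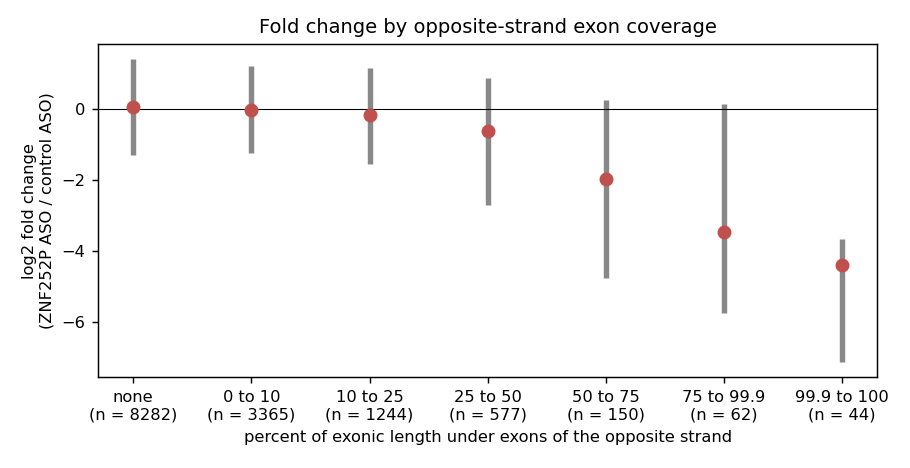
Log2 fold change (ZNF252P ASO over control ASO) against the percent of a gene's exonic length under exons of the opposite strand, with points for the median and bars from the 10th to the 90th percentile of genes, and genes without reads in a group set at a floor of 3 counts over that group. The median was 0.067 with no coverage and -1.97 at 50 to 75% coverage.

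**Figure D3:**
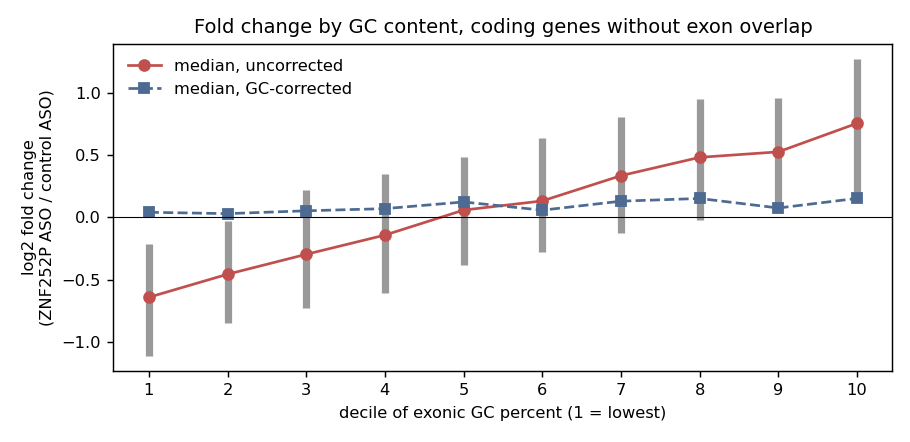
Median log2 fold change (ZNF252P ASO over control ASO) in each decile of exonic GC percent for 5520 coding genes without exon overlap, before and after the GC correction, with bars for the quartiles before correction. The uncorrected median rose from -0.64 to 0.75, and the correction is built to remove such a trend.

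Among the 10 largest rises were 4 pseudogenes, RPL12P14, TSSK5P, BEND3P1 and MTX1P1. Reads of RPL12P14, BEND3P1 and MTX1P1 could be shared with near-identical copies, and their levels are therefore uncertain. TSSK5P is annotated as a unitary pseudogene, and its level is uncertain too, since the source of its reads was not tested. RPL12P14 had 0 reads in the control ASO libraries and 574 in the others, at least 205.9-fold higher against a floor of 3 counts over the group. TSSK5P and BEND3P1 had 2 control reads each, for ratios of 274.4 (95% exact interval 75.58 to 2272) and 262.1 (72.16 to 2170). FLG, which encodes the skin barrier protein filaggrin, had 3 control reads and a ratio of 226.4 (77.1 to 1101). DIO2, a deiodinase that activates thyroid hormone, rose 121-fold to 17.2 ± 1.75 CPM (SD, n = 3), and CPA4, a carboxypeptidase, rose 83.9-fold. PLEKHG6, HRNR and MTX1P1 rose 79.27-fold, 66.4-fold and 79.29-fold. DIO2 had 8 control reads, CPA4 had 4, PLEKHG6 and HRNR had 5 each and MTX1P1 had 7, so the size of these edgeR folds is uncertain. The mitochondrial tRNA gene MT-TP, on the light strand, rose 59.45-fold, from 1.54 to 91.5 CPM. Its reads cannot be told from those of the opposite strand, since the strand of the counting is not given. Adjusted p-values of these 10 rises in edgeR were at most 1.2e-11. Whether a difference in counting by strand between the groups bears on them was not tested. Among the 8282 genes with no opposite-strand exon and under 2% same-strand overlap, 25 had no control read. In the same class, 4 had no read in the ZNF252P ASO libraries.

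Among the 10 largest falls, 7 genes have opposite-strand exons over 35 to 100% of their exonic length. GJD3-AS1, SFT2D3, ZNF593, EVA1B and PHLDA1-AS1 had 0 reads in the ZNF252P ASO libraries and were at least 499.9-fold, 470.5-fold, 273.8-fold, 153.9-fold and 103.1-fold lower against the same floor. MIF, which encodes a cytokine that inhibits macrophage migration, had 2 reads against 982, for a ratio of 456.2 (126 to 3773), and EML2-AS1 had 1 read against 427, for a ratio of 396.8 (70.83 to 15710). The remaining 3 have no opposite-strand exon in GENCODE 29. That release holds 58396 of the 60664 gene IDs, and exons of the other IDs were not seen. NELFCD, a subunit of the negative elongation factor, fell 300.8-fold, from 40.6 ± 4.84 to 0.124 ± 0.0732 CPM (SD, n = 3). The chemokine gene CCL20 fell 283-fold and GPATCH4 fell 217-fold. Ranking only genes with no opposite-strand exon, a choice made after seeing the data, added TXNIP (146-fold), CLEC4E (2 reads against 305, for a ratio of 141.7 with an interval from 38.89 to 1175), CEACAM6 (112-fold), NTS (78.3-fold), CNTNAP2 (57.9-fold), DHRS2 (50.1-fold) and ULBP1 (45.8-fold) to the falls. TXNIP encodes an inhibitor of thioredoxin, CEACAM6 a cell surface adhesion protein, NTS the peptide neurotensin and ULBP1 a ligand of the NKG2D receptor. It added FAM222A (43.7-fold) and CEND1 (43.3-fold) to the rises. In edgeR, the adjusted p of each of these falls and rises was at most 8.2e-07.

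Of 33 gene lists fixed before the data were examined, 31 had enough measured members for a test, and 13 passed it (camera with a preset correlation of 0.01, adjusted p under 0.05). Splits of the 6 libraries that mix the groups put 5 to 12 lists past the same test with 0 genes called. Passing it therefore does not by itself tell the real grouping from a mixed one. With a correlation estimated from these 6 libraries, none of the 31 passed at an adjusted p under 0.05 in camera, and 3 had an unadjusted p under 0.05. Among the 13, the estimated correlations ran from -0.014 for apoptosis regulators to 0.62 for hypoxia genes. In fry, which asks whether members move one way without comparing them with other genes, 29 passed. Without the filter on low counts, 6 lists that had missed the threshold passed it in camera, with adjusted p-values of 0.0447 for MYC network members, 0.0447 for ribosome biogenesis factors, 0.0206 for p53 targets, 0.0177 for fatty acid synthesis, 0.0198 for epithelial genes and 0.015 for ERK feedback genes. Counts of members adjusted over the list alone equalled those over all genes tested, except in the 3 lists where both are given.

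**Figure D4:**
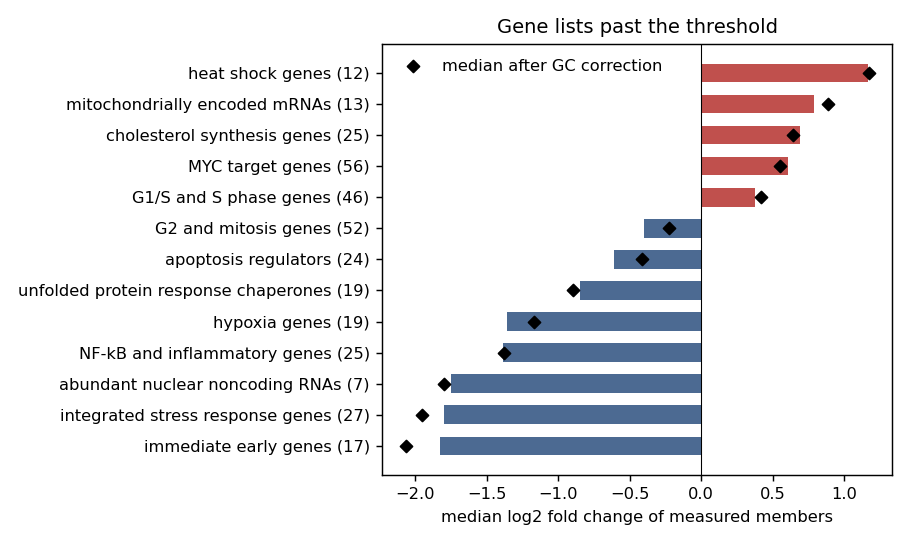
Median log2 fold change (ZNF252P ASO over control ASO) of the measured members of the 13 gene lists past the threshold, with the number of members in brackets and diamonds for the median after the GC correction. MYC target genes had a median of 0.61 and integrated stress response genes one of -1.80.

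MYC target genes, the second subject of the comparison, were mostly higher although MYC itself was lower. Of 56 measured members, 42 rose, 7 fell and 7 did not pass, with a median log2 fold change of 0.61 (camera, adjusted p = 4.31e-05, and adjusted p = 0.40 with an estimated correlation). MYBBP1A, which encodes a nucleolar Myb-binding protein, rose 3.51-fold, and the replication helicase genes MCM5 and MCM4 rose 4.06-fold and 2.785-fold. CDK4, which drives the G1 phase, fell 1.56-fold, and opposite-strand exons cover 43.2% of it. HK2 had the largest change of the list and fell 14.9-fold, from 57.6 ± 23.5 to 3.86 ± 0.482 CPM (SD, n = 3). Opposite-strand exons cover 0.115% of HK2. Over the 30 targets with no opposite-strand exon, 23 rose and 2 fell (camera, adjusted p = 0.000451). Ribosome biogenesis factors went both ways, with 27 of 50 higher and 14 lower (camera, adjusted p = 0.0822, and 0.00444 as an adjusted p with the GC correction). This list did not pass with the GC correction and an estimated correlation (camera, adjusted p = 0.323), nor over genes with no opposite-strand exon without and with the GC correction (camera, adjusted p = 0.244 and 0.136). RRS1 and RRP1B rose 5.23-fold and 2.70-fold.

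The MYC network members are MYC relatives, MAX, MLX and proteins that pair with MAX or MLX. Of 11 measured, 8 fell and 2 rose, and the list did not pass (camera, adjusted p = 0.115). MXI1, which encodes a repressor that competes with MYC for MAX, fell 7.45-fold, from 88.5 to 11.8 CPM, and MYCL fell 4.70-fold. MNT, MLXIPL, MXD1, MAX, MGA and MXD3 had log2 fold changes of -1.70, -1.71, -1.02, -0.66, -0.35 and -0.35. MXD4 rose 4.90-fold and MLXIP 1.63-fold, and MLX had a log2 fold change of 0.089 (edgeR, adjusted p = 0.245). With the GC correction MGA did not pass (edgeR, adjusted p = 0.435). The call of MXD3 was lost without control ASO replicate 1, ZNF252P ASO replicate 1 or ZNF252P ASO replicate 3 (edgeR, adjusted p = 0.061, 0.0961 and 0.0534), and in DESeq2 (adjusted p = 0.0645).

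Genes of the G1/S transition and S phase were mostly higher and those of G2 and mitosis mostly lower. In the first list 31 of 46 rose and 10 fell, with a median of 0.37 (camera, adjusted p = 0.0208, and adjusted p = 0.50 with an estimated correlation). E2F1, a transcription factor of S phase entry, rose 2.95-fold, MCM7 2.33-fold and the flap endonuclease gene FEN1 2.21-fold. TYMS, the thymidylate synthase gene, fell 2.73-fold with 46.6% of it under opposite-strand exons. In the second list 34 of 52 fell and 10 rose, with a median of -0.40 (camera, adjusted p = 0.00858, and adjusted p = 0.60 with an estimated correlation), and its call was lost with the GC correction, where the median was -0.23 (camera, adjusted p = 0.0819). Over genes with no opposite-strand exon it passed without and with the GC correction (camera, adjusted p = 0.0111 and 0.0354). SMC4, a condensin subunit gene, fell 3.89-fold, GAS2L3 3.55-fold and ANP32E 3.01-fold, and the tubulin gene TUBB4B rose 4.055-fold. With the GC correction their log2 fold changes were smaller, at -1.32, -1.01, -0.88 and 1.57.

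The p53 target genes and apoptosis regulators held members in both directions. Of 30 p53 targets, 19 rose and 9 fell, and the list did not pass (camera, adjusted p = 0.0545). It passed without control ASO replicate 2 and without ZNF252P ASO replicate 2 (camera, adjusted p = 0.0474 and 0.0467) and with the GC correction (camera, adjusted p = 0.0355). With an estimated correlation it did not pass (camera, adjusted p = 0.446, with and without the GC correction), nor over genes with no opposite-strand exon without and with the GC correction (camera, adjusted p = 0.0825 and 0.062). TP53I3 and PLK2 rose 4.68-fold and 4.11-fold. Of 24 apoptosis regulators, 16 fell and 6 rose, with a median of -0.61 (camera, adjusted p = 0.0298, and adjusted p = 0.39 with an estimated correlation). HRK, which promotes cell death, fell 8.89-fold, while BIRC3 and BCL2L1, which oppose it, fell 2.62-fold and 1.98-fold, and opposite-strand exons cover 43.0% of BCL2L1. BAX, which promotes cell death, rose 2.59-fold. The GC-corrected log2 fold changes were -3.26 for HRK, -0.57 for BIRC3, -1.36 for BCL2L1 and 0.94 for BAX. The list's call was lost over genes with no opposite-strand exon once the GC correction was added (camera, adjusted p = 0.136).

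Genes of the integrated stress response, the program of amino acid shortage and blocked translation, were mostly lower. Of 27 members, 23 fell and 2, SLC7A5 and SESN2, rose, with 24 lower and 2 higher adjusted over the list alone. The median was -1.80 (camera, adjusted p = 6.18e-06, and adjusted p = 0.28 with an estimated correlation). MTHFD2, an enzyme of mitochondrial folate metabolism, fell 6.75-fold from 669 ± 2.35 to 99.1 ± 1.72 CPM (SD, n = 3). CEBPB, a transcription factor gene, fell 4.39-fold, DDIT4, an inhibitor of mTORC1 signalling, fell 4.19-fold, and the amino acid transporter gene SLC7A5 rose 2.00-fold. Opposite-strand exons cover 33.2% of MTHFD2 and 41.2% of DDIT4, and among the 18 members with none, 16 fell and 1 rose (camera, adjusted p = 8.2e-05).

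Of 19 unfolded protein response genes of the endoplasmic reticulum, 14 fell and 4 rose, or 14 and 5 adjusted over the list alone, with a median of -0.85 (camera, adjusted p = 0.0173, and adjusted p = 0.39 with an estimated correlation). HERPUD1, HSP90B1 and XBP1 fell 4.216-fold, 3.418-fold and 3.035-fold, and CALR, the calreticulin gene, rose 1.78-fold. Over the 9 members with no opposite-strand exon the median was -1.12 and the list did not pass (camera, adjusted p = 0.067), but it passed over them with the GC correction (camera, adjusted p = 0.0203). Of 12 heat shock genes 10 rose, HSPA4L and CRYAB did not pass, and the median was 1.17 (camera, adjusted p = 0.00154, and adjusted p = 0.43 with an estimated correlation). HSP90AA1, the inducible cytosolic HSP90 gene, rose 4.42-fold from 497 to 2196 CPM, and DNAJB1 and HSP90AB1 rose 2.33-fold and 2.17-fold.

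Hypoxia genes were mostly lower, with 17 of 19 down, P4HA2 and EGLN1 up and a median of -1.36 (camera, adjusted p = 0.00256, and adjusted p = 0.50 with an estimated correlation). VEGFA, the vascular endothelial growth factor gene, fell 3.175-fold, BHLHE40 2.90-fold and INSIG2 3.64-fold, and the oxygen sensor gene EGLN1 rose 2.27-fold. The GC-corrected log2 fold changes were -1.96 for VEGFA, -1.74 for BHLHE40, -1.10 for INSIG2 and 1.35 for EGLN1. The list did not pass over genes with no opposite-strand exon once the GC correction was added (camera, adjusted p = 0.0535). Glycolysis genes went both ways, with 12 of 22 higher and 6 lower (camera, adjusted p = 0.285), a median of 0.19 and a mean of -0.034. After the GC correction 11 were higher and 10 lower (camera, adjusted p = 0.818). PKM, the pyruvate kinase gene, rose 2.88-fold and the glucose transporter gene SLC2A3 fell 4.46-fold. Of 30 NRF2 target genes 16 rose and 8 fell (camera, adjusted p = 0.157), with OSGIN1 5.095-fold and the heme oxygenase gene HMOX1 4.795-fold higher.

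Of 25 NF-kB and inflammatory genes 17 fell, while BCL3, NFKB1, TNIP1, RELB and NFKBIE rose, with a median of -1.39 (camera, adjusted p = 0.00226, and adjusted p = 0.40 with an estimated correlation). The neutrophil chemokine genes CXCL8 and CXCL5 fell 30.2-fold, from 83.9 to 2.79 CPM, and 6.97-fold, from 738 to 106 CPM. NFKBIE, an inhibitor of NF-kB, rose 1.925-fold. The GC-corrected log2 fold changes were -4.01 for CXCL8, -2.19 for CXCL5 and 0.45 for NFKBIE. With the GC correction TNIP1, RELB and BCL3 were lower, at -0.14, -0.31 and -0.51 on the log2 scale, and NFKB1 did not pass. Of 17 immediate early genes 14 fell, SRF and FOSL1 rose, and the median was -1.83 (camera, adjusted p = 0.0018, and adjusted p = 0.44 with an estimated correlation). IER2, BTG1 and IER3 fell 6.05-fold, 5.82-fold and 4.80-fold, with opposite-strand exons over 30.8% of IER2 and 26.5% of IER3, and FOSL1 rose 1.77-fold. SRF was lower with the GC correction, at -0.33 on the log2 scale. ERK pathway feedback genes did not pass, with 12 of 18 lower and FOSL1, CCND1 and EPHA4 higher (camera, adjusted p = 0.0631). They passed without control ASO replicate 2 (camera, adjusted p = 0.0448), with the GC correction (camera, adjusted p = 0.0442) and over genes with no opposite-strand exon (camera, adjusted p = 0.0352). With an estimated correlation they did not pass (camera, adjusted p = 0.50, and 0.446 as an adjusted p with the GC correction). DUSP5 and EREG fell 6.27-fold and 3.94-fold. Interferon-stimulated genes were split, with 6 of 20 higher and 6 lower (camera, adjusted p = 0.752), including OAS3 (1.82-fold higher) and OAS1 (2.07-fold lower).

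Genes of sterol and fatty acid synthesis were mostly higher. Of 25 cholesterol synthesis genes 17 rose, STARD4 and SC5D fell, and the median was 0.69 (camera, adjusted p = 0.00634, and adjusted p = 0.44 with an estimated correlation). DHCR7 and FDFT1, enzymes of the pathway, rose 4.47-fold and 2.67-fold, and the sterol carrier gene STARD4 fell 2.76-fold. SC5D did not pass with the GC correction, nor did ACSL3 of the next list. Of 12 fatty acid synthesis genes 8 rose and ACSL3 fell, and the list did not pass (camera, adjusted p = 0.0538). It passed without control ASO replicate 2 (camera, adjusted p = 0.0459) and with the GC correction (camera, adjusted p = 0.0102). With an estimated correlation it did not pass (camera, adjusted p = 0.395, and 0.24 as an adjusted p with the GC correction). Its adjusted p in camera over genes with no opposite-strand exon was 0.237, and 0.0466 with the GC correction. The fatty acid synthase gene FASN rose 4.19-fold and ACLY 2.25-fold.

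Of 13 mitochondrially encoded mRNAs 11 rose and MT-ND4 fell, with a median of 0.79 (camera, adjusted p = 0.00568, and adjusted p = 0.45 with an estimated correlation). MT-ND6, the only mRNA of this list encoded on the light strand, rose 4.32-fold, MT-ND2 2.16-fold and MT-ND1 1.99-fold. Since the strand of the counting is not given, reads of MT-ND6 cannot be told from those of the opposite strand. MT-ND4 had a log2 fold change of -0.15, whose call was lost without control ASO replicate 3 or ZNF252P ASO replicate 1 (edgeR, adjusted p = 0.0641 and 0.121) and whose sign turned with the GC correction. Mitochondrial genes took 5.06 ± 0.185% of counts in the ZNF252P ASO libraries and 4.07 ± 0.116% in the control ASO libraries (SD, n = 3). Nuclear oxidative phosphorylation genes did not pass, with 21 of 38 higher and 10 lower (camera, adjusted p = 0.0951). NDUFS7 and UQCRQ fell 7.52-fold and 3.01-fold with 49.1% and 20.8% of them under opposite-strand exons.

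Of 71 cytosolic ribosomal protein genes 37 rose and 18 fell (camera, adjusted p = 0.0822), with RPS23 5.46-fold and RPS3A 2.85-fold lower. Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, had 8 of 13 members higher and H1-3 lower, or 7 higher adjusted over the list alone (camera, adjusted p = 0.0822). This list passed when tested over genes with a CPM of at least 1 in 3 libraries (camera, adjusted p = 0.0268), though not over the genes of the other tests with an estimated correlation (camera, adjusted p = 0.433), and H2BC4 and H2BC12 rose 11.4-fold and 5.20-fold. The list named abundant nuclear noncoding RNAs is not limited to nuclear RNAs. Of its 7 measured members 6 fell and RN7SL1 did not pass, with a median of -1.75 (camera, adjusted p = 0.00841, and adjusted p = 0.39 with an estimated correlation). The snoRNA host genes SNHG1, GAS5 and SNHG8 fell 5.10-fold, 4.50-fold and 3.26-fold.

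Lineage and junction genes moved in both directions. Of 20 epithelial junction and keratin genes 12 fell, PKP3, KRT8, JUP, CLDN2 and KRT19 rose, and the list did not pass (camera, adjusted p = 0.123, and 0.0355 as an adjusted p with the GC correction). The list did not pass with the GC correction and an estimated correlation (camera, adjusted p = 0.323), nor over genes with no opposite-strand exon without and with the GC correction (camera, adjusted p = 0.195 and 0.0888). The tight junction gene CLDN1 fell 2.49-fold and JUP, the plakoglobin gene, rose 2.41-fold. PKP3 did not pass with the GC correction, nor did MUC1 among the alveolar markers. Of 26 mesenchymal and matrix genes 12 rose and 9 fell (camera, adjusted p = 0.276), with the collagen gene COL5A1 5.82-fold and the thrombospondin gene THBS1 3.67-fold higher. Of 22 YAP and SRF target genes 10 rose and 8 fell (camera, adjusted p = 0.998), with FJX1 7.71-fold higher and FSTL1 2.76-fold lower, and 7 were higher and 10 lower with the GC correction (camera, adjusted p = 0.462). Of 5 alveolar type 2 markers ABCA3 and MUC1 rose and LAMP3 and NAPSA fell (camera, adjusted p = 0.951), by 1.74-fold for ABCA3 and 8.38-fold for LAMP3.

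Of 4 measured fibroblast markers THY1 rose 14.8-fold, from 0.486 to 7.35 CPM, and COL1A1 rose 1.805-fold, from 16.8 to 30.3 CPM (camera, adjusted p = 0.18). Of 6 markers of squamous and other carcinoma lines SOX2, CDX2, TP63 and HNF4A rose and LIN28B fell (camera, adjusted p = 0.164), with SOX2 12.6-fold higher at 11.9 CPM and HNF4A 1.27-fold higher, at 56.9 against 44.7 CPM, a call that HNF4A lost with the GC correction (edgeR, adjusted p = 0.129). LIN28B was higher with the GC correction, at 0.29 on the log2 scale. CD14 was the 1 measured leukocyte marker, at 4.88 against 0.732 CPM, and 0 of the 8 endothelial markers had enough reads to be tested.

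Near ZNF252P at 8q24.3, 5 of 10 measured neighbours rose and 4 fell (camera, adjusted p = 0.64), with a median of 0.21 and a mean of -0.025. After the GC correction 1 was higher and 5 were lower, with a median of -0.25 (camera, adjusted p = 0.368). ZNF252P-AS1, which runs antisense to the target, fell 3.85-fold at 0.256 against 1.01 CPM, and with the strand of the counting not given its reads cannot be told from those of ZNF252P where they overlap. ZNF34, ZNF250 and ZNF7 had log2 fold changes of -0.52, -0.42 and -0.42. COMMD5 rose 2.455-fold and ARHGAP39 1.63-fold, and ARHGAP39 did not pass with the GC correction (edgeR, adjusted p = 0.275). RPL8, ZNF517 and ZNF16 had log2 fold changes of 0.32, 0.31 and 0.31, which were -0.24, -0.26 and 0.14 with the GC correction. Calls were lost for ZNF16 without control ASO replicate 1 or 3 (edgeR, adjusted p = 0.108 and 0.138) or ZNF252P ASO replicate 1 or 2 (0.176 and 0.132), with library totals (0.0744), without the filter (0.0518) and in DESeq2 (0.117), and for ZNF517 without control ASO replicate 1 or ZNF252P ASO replicate 2 (edgeR, adjusted p = 0.0674 and 0.135) and in DESeq2 (0.0891). Neither passed over genes with no opposite-strand exon (edgeR, adjusted p = 0.117 for ZNF16 and 0.0826 for ZNF517) or over all genes with the GC correction (edgeR, adjusted p = 0.342 and 0.0635). C8orf33 had a log2 fold change of 0.12 (edgeR, adjusted p = 0.094), which passed without ZNF252P ASO replicate 1 (edgeR, adjusted p = 0.0214).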

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

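The restrictions to genes with no opposite-strand exon and the GC correction were chosen after seeing the data. ZNF252P and MYC stayed lower and past the threshold in the alternatives that tested them, between -1.78 and -1.39 for ZNF252P and between -1.37 and -0.93 for MYC on the log2 scale. ZNF252P itself has opposite-strand exons and was not in the runs without such genes. Leaving out 1 library at a time gave 5734 to 6001 genes higher and 5839 to 6152 lower, 2388 to 2466 and 2669 to 2779 at 2-fold, log2 fold changes from -1.77 to -1.70 for ZNF252P and from -1.15 to -0.93 for MYC, adjusted p-values from 1.74e-05 to 0.000114 in camera for MYC target genes, and 13 to 16 lists past the threshold.

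Gene counts moved by over 1.5 times only where fewer genes were tested, while list counts moved by more with other list tests. Over the 9347 genes with no opposite-strand exon, 3593 were higher and 3513 lower, 1480 and 1465 of them by at least 2-fold, and with the GC correction added the counts were 3484, 3397, 1172 and 1276. DESeq2 size factors, library totals and upper-quartile factors changed the share of called genes that were higher from 49.41% to 50.02%, 47.81% and 49.42%. With an estimated correlation 0 lists passed in camera, against 13 with the preset correlation, and MYC target genes had an adjusted p of 0.40, while fry passed 29 lists. The cause of these shifts was not tested. Of the other 30 lists, 12 lost their call with the estimated correlation. Unfolded protein response genes, apoptosis regulators and abundant nuclear noncoding RNAs were among them. Their estimated correlations were -0.0067, -0.014 and 0.0046, below the preset 0.01. A correlation larger than the preset one therefore cannot account for the loss in these lists.

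With the GC correction 480 genes were called in the opposite direction, and 318 over genes with no opposite-strand exon with that correction. Among the genes named by rule RPL8 was called in the opposite direction with the GC correction, at -0.24 on the log2 scale, while ZNF517 at -0.26, MT-ND4 at 0.014, MLX at -0.10 and C8orf33 at -0.048 changed sign without a call. Over genes with no opposite-strand exon with the GC correction RPL8 at -0.32, ZNF517 at -0.33 and C8orf33 at -0.13 passed in the opposite direction. The YAP and SRF target genes passed in the other direction in fry (adjusted p = 0.0204). The cause was not tested.

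With the replicate block, 5956 genes were higher and 6065 lower, against 6012 and 6156 without it. Deviations of libraries with the same number correlated at -0.0127, -0.0119 and 0.0167, so the numbers show no pairing, and not every library correlated best with its own number. The block changed no call of a named gene or list.

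On simulated counts 1.5-fold changes were recovered for 46 of 67 genes, and recovery by read count was not tested.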

Other observations

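The counts by gene type come from the fit of all 15743 genes, not from the separate fit of the 9347 genes with no opposite-strand exon. Among genes with no opposite-strand exon, processed pseudogenes had 230 of 438 members higher in the ZNF252P ASO libraries and 64 lower (edgeR, adjusted p under 0.05). Their median log2 fold change was 0.53. Long intergenic noncoding RNAs had 195 of 469 lower and 104 higher and a median of -0.40. Transcribed unprocessed pseudogenes, the type of ZNF252P, which itself has opposite-strand exons and is not counted here, had 18 of 131 higher and 48 lower and a median of -0.32. Antisense genes had 57 of 201 higher and 64 lower and processed transcripts 15 of 56 higher and 21 lower, with medians of -0.11 and -0.19. For protein-coding genes the median was 0.094, with 3339 of 7713 higher and 2759 lower. Reads of processed pseudogenes can be shared with their parent genes.

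Of the tRNA genes on the light strand of the mitochondrial genome, MT-TP rose to 91.5 CPM from 1.54 CPM and MT-TC to 0.965 CPM from 0.0184 CPM, while MT-TQ and MT-TS1, at 2.77 and 2.73 CPM in the control ASO libraries, had no read in the ZNF252P ASO libraries. These genes were chosen after their values were seen. Their reads cannot be told from those of the opposite strand, since the strand of the counting is not given.

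The tests below were chosen after the results were seen, except those on antisense-type genes, on ZNF252P among genes of like coverage and on other splits of the libraries.

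The first pattern is the absence of reads in the ZNF252P ASO libraries from 41 of 44 genes whose exons lie wholly under opposite-strand exons. Lower depth is excluded, since the control level predicts a median of 69.2 reads per gene. A loss of antisense-type transcripts in general is argued against, since 0% of 332 such genes with under 10% coverage and control reads in the same range were without reads. Only genes kept by the expression filter were compared. Genes with few control reads and none in the ZNF252P ASO libraries could not be among the 332, so for such genes this loss stays open. Discarding same-strand overlaps in the ZNF252P ASO libraries alone is argued against by a median log2 fold change of 0.021 over 263 genes with 25 to 75% same-strand coverage. If the control ASO libraries also lost reads in same-strand overlaps, that median would be the same. The counting program is not given, so discarding overlaps whatever their strand stays open. A candidate explanation is that reads were counted by strand in the control ASO libraries and without strand in the others, since 727 genes with 25 to 75% opposite-strand coverage, which are not part of the pattern, had a median of -0.77. Against it, CFAP126 and TRIM8-DT had more reads despite full coverage, 368 against 22 and 365 against 36, and HTATSF1P2 had 104 against 495. Whether a difference in strand counting also bears on genes that rose was not tested.

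The second pattern is the lower count of ZNF252P. A GC trend as the whole cause is argued against by its log2 fold change of -1.39 after the GC correction. Loss of reads under opposite-strand exons stays open, since ZNF252P stood at percentile 7.06 of the fold changes of 2436 genes with 5 to 20% coverage, whose median was -0.081. A difference in preparation, sequencing or counting between the groups cannot be told apart from the ASO, because it goes with the group and 77.29% of genes differed. The effect of the ASO itself, which the design names, remains open beside it.

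The third pattern is lower MYC with higher MYC target genes. A GC trend as the whole cause is argued against by the list's adjusted p of 1.89e-05 in camera after the GC correction, with MYC still lower, though with an estimated correlation the list did not pass (adjusted p = 0.323). Opposite-strand exons are argued against by an adjusted p of 0.000451 in camera over targets with none, and MYC has none. A difference in preparation, sequencing or counting cannot be told apart from the ASO, since the first principal component, with 90.8% of the variance, parts the groups. The effect of the ASO remains open as well.

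The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 12168 genes, 5174 of them by at least 2-fold. The highest of the other splits called 0 in edgeR, where at most 32 had an unadjusted p under 0.05. Each other split mixes libraries of both groups, so the difference between the groups becomes spread within each set. Few gene calls there were bound to follow, and the gene counts cannot weigh chance. The real split put 13 lists past the threshold in camera, and the others put 5 to 12 past it with 0 genes called. In each of these counts 1 of the 10 splits, the real one, gave a result as large.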
